A study of Rattus norvegicus with 6 samples.

How the data were processed

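Gene expression was measured by RNA sequencing in 6 libraries, 3 from apical-turn and 3 from basal-turn outer hair cells of postnatal day 9 rats. Per the labels' protocols, each turn was digested with 1 mg/ml collagenase IV for 10 min, 30 outer hair cells were collected for each library, RNA was extracted with Trizol, and libraries were made with the NEBNext Ultra RNA kit. Strand is not recorded by that kit as named, so reads of overlapping antisense genes cannot be told apart. How RNA of so few cells was amplified is not given in the sources used here. Bowtie2 2.2.3 and TopHat2 2.0.12 were used by the authors, per the submitters' processing notes. The genome build, annotation, counting tool and differential test are not given in the sources used here, and coordinates are those of the deposited table on its unnamed build.

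The deposited table holds whole-number read counts per gene and library for 35790 genes, per the file headers, of which 32754 carry Ensembl identifiers and 3036 identifiers of unannotated loci. It also holds FPKM values made by the authors; for 69.4% to 70.3% of genes with over 20 counts these equalled the count divided by gene length and library total within a relative difference of 1e-06. The authors' mean normalized counts, a normalized signal per group, equalled counts divided by median-of-ratios size factors for 100% of genes with a value above 0 in basal libraries, at the same tolerance. The authors' deposited log2 fold changes and p-values for basal against apical cells were used only where named as theirs. GO annotations were read from the same table.

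Counts were analysed as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which left 13507, and libraries were scaled by TMM. The quasi-likelihood test (glmQLFit, glmQLFTest) compared basal with apical libraries with no covariate, with Benjamini-Hochberg adjustment over all genes tested. The planned test named no further option, and the default of this version was kept as the main result. A bias-adjusted form had been fitted first, so this choice was made after the calls of both forms had been seen. Standard errors of log2 fold changes were taken as the log2 fold change divided by the square root of the test's F. Gene lists were tested with camera (limma 3.58.1) on log2 CPM (counts scaled to a common library size) with a prior count of 2, at a preset correlation of 0.01, with an estimated correlation, and with fry. The p of fry for a shared direction was used unless its mixed form is named. Sums of CPM over lists were compared by exact permutation tests; 3 against 3 cannot go below p = 0.1. DESeq2 1.42.0, limma-voom with and without sample weights, and limma with a trend on log2(FPKM + 1) for genes with an FPKM of at least 1 in at least 3 libraries were alternatives. Python tables used pandas 2.3.3 and numpy 2.4.6, and plots used matplotlib 3.10.9.

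The groups, tests, alternatives, the 27 gene lists and the rule for named genes were chosen before the data were examined. The rule names 11 hair cell genes in any case, of which 1 is not reported here, 10 genes in each direction, and members of each list. For each direction it takes passing genes first, then those of smallest p with non-overlapping groups and a mean of at least 20 counts in the higher group. For each list it takes at most 4 passing members, or at most 2 of smallest p where none passed. Of the listed symbols, 765 were matched, 18 of them through older symbols in a RefSeq gene table for assembly GRCr8 that was used only for names, and 43 were not matched. Oncomodulin is listed as Ocm2. Where rows shared a symbol, the row with the highest total count was used.

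The tests were checked on counts simulated for the 13507 genes with 50 genes changed at each of 4 sizes. The changed genes were drawn only from those with high mean counts, so the numbers recovered do not cover genes with few counts. The edgeR quasi-likelihood test recovered 0, 16, 31 and 32 of 50 genes changed by 4-fold, 16-fold, 64-fold and 256-fold, with 3 unchanged genes called. The bias-adjusted form recovered 2, 27, 41 and 42 with 25 unchanged genes called, and DESeq2 recovered 6, 29, 40 and 38 with 216 unchanged genes called. In a second simulation a list of 40 genes raised by 1.5 on the log2 scale had a camera p of 1.06e-10. There 0 of 20 random lists were called, while the raised list had an adjusted p of 0.126 with an estimated correlation. Genes were drawn independently of each other, so this cannot show how often the preset correlation calls lists whose genes vary together.

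Alternatives covered other scalings, count filters, robust dispersions, the replicate number as a block, each library left out in turn, and removal of mitochondrial, ribosomal protein and red blood cell genes. Further alternatives were added after seeing the data: the bias-adjusted test, the likelihood ratio test, removal of genes of other cell types, the Schwann cell sum as a covariate, basal replicates 2 and 3 left out, and GO terms of 10 to 500 tested genes. The planned pseudocount of 0.1 applied only to a main test on normalized values and was not run. CPM of single genes use TMM-scaled library sizes, and list shares and the plot of named genes use total counts. Ratios against groups with 0 to 3 counts use a floor of 3 counts over the group or a 95% exact binomial interval.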

Results

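RNA sequencing was carried out on outer hair cells of the rat cochlea, the electromotile sensory cells that amplify sound-driven vibration in the inner ear. The animals were wild-type Sprague-Dawley rats at postnatal day 9. Cells came either from the apical turn of the cochlea, which is tuned to low frequencies, or from the basal turn, which is tuned to high frequencies. Each library was made from 30 cells picked under a microscope, and there were 3 apical and 3 basal libraries. The sources used here do not say whether the 3 libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical. Total gene counts were 22849274, 18617323 and 23140976 in apical replicates 1, 2 and 3 and 18459189, 16511675 and 20301499 in basal replicates 1, 2 and 3. Between 11244 and 16333 genes had at least 1 count in a library, and 3 counts corresponded to 0.130 to 0.182 CPM (counts scaled to a common library size).

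Correlations between libraries were higher among apical than among basal libraries, a difference that was not tested. Over 13507 genes, Pearson's r of log2 CPM averaged 0.747 ± 0.059 (SD, 3 pairs) among apical libraries and 0.563 ± 0.056 (SD, 3 pairs) among basal libraries. Between the groups it averaged 0.595 ± 0.051 (SD, 9 pairs), which lies within the spread of the basal pairs. Over the 1000 genes of highest expression it averaged 0.789 among apical, 0.604 among basal and 0.551 between libraries of different groups, so the order of the last values turned. These correlations are across genes, which are not independent replicates. The most abundant gene was Calb1 (calbindin), Mt-cox3 and Skp1 in apical replicates 1, 2 and 3, and Ocm2, Mt-cox3 and Ibsp (bone sialoprotein) in basal replicates 1, 2 and 3.

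The comparison of basal with apical cells asks how expression differs between these sub-populations, which the study relates to differences in their structure, function and vulnerability. In the basal libraries, genes of myelinating Schwann cells rose as a group by camera, with all 13 of 13 tested members higher and a median log2 fold change of 6.75 (adjusted p = 0.596 with an estimated correlation). Markers of macrophages and of red blood cells rose as groups too, with medians of 3.50 and 2.46 (adjusted p = 0.596 with an estimated correlation for each). Genes of mechanotransduction and the stereocilia, the hair bundle that detects sound, fell as a group, with 36 of 43 members lower and a median of -0.73 (adjusted p = 0.596 with an estimated correlation). General hair cell genes fell as a group, with 17 of 21 members lower and a median of -0.91 (adjusted p = 0.596 with an estimated correlation). Both hair cell calls were lost without basal replicate 3 (medians -0.31 and -0.53, adjusted p = 0.313 and 0.794), and the medians moved to -1.74 and -1.57 without basal replicate 1. By edgeR's quasi-likelihood test no single gene passed an adjusted p of 0.05, while DESeq2 called 663 genes. For single genes, passing below refers to the edgeR test unless another is named.

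By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 13507 genes passed. An unadjusted p under 0.05 was found for 811, of which 287 were higher in basal and 524 higher in apical libraries. That count was 708 to 1707 with a library left out, reaching 1484 without basal replicate 1 and 1707 without basal replicate 3. DESeq2 called 663 genes, 270 higher in basal and 393 higher in apical libraries, and in 267 of these every library of one group had a count of 0. The DESeq2 count was 1231 without basal replicate 1 and 1703 without basal replicate 3. Its balance turned without apical replicates 1, 2 and 3, with 692, 493 and 525 genes higher in basal and 190, 263 and 175 higher in apical libraries. Without basal replicates 1, 2 and 3 it gave 448, 250 and 277 higher in basal and 783, 540 and 1426 higher in apical libraries. A bias-adjusted form of the quasi-likelihood test called 28 (189 without basal replicate 1 and 0 without any of the other 5 libraries), the edgeR likelihood ratio test 327, and limma-voom, limma-voom with sample weights and limma on FPKM values each called 0. The authors' deposited table lists 107 genes with an adjusted p under 0.05, 52 higher in basal and 55 higher in apical cells, and 94 of them were among the DESeq2 calls. The libraries of the groups did not overlap for 2128 genes (15.8%, where chance gives 10%), of which 730 were higher in basal and 1398 higher in apical libraries. Camera with a preset correlation called 10 of the 27 gene lists, 8 higher and 2 lower in basal libraries, and with an estimated correlation it called 0, the lowest adjusted p being 0.596. With basal replicates 2 and 3 left out camera called 5 lists and edgeR 289 genes. That fit sets 3 apical libraries against 1 basal library, which is assumed to vary like the apical ones.

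Schwann cell and glia markers held the largest median difference of the 27 lists (camera adjusted p = 3.33e-16; adjusted p = 0.596 with an estimated correlation). By edgeR's quasi-likelihood test 10 of the 13 members passed adjusted over the list alone, all higher in basal libraries, against 0 over all genes. DESeq2 called 9 members over all genes. Prx (periaxin, a protein of the myelin sheath; ENSRNOG00000018369, chromosome 1, 84304228 to 84324560) had 1, 1 and 0 counts in the apical libraries and 585, 9368 and 5268 in the basal libraries. The ratio of its summed rates was 8896 (95% interval 2462 to 73463, which covers counting error only). Pmp22 (peripheral myelin protein) had a log2 fold change of 6.77 (SE 1.17) and Mbp (myelin basic protein) one of 6.75 (SE 1.20). Neither passed by edgeR's quasi-likelihood test (adjusted p = 0.438 for each), while both passed by DESeq2 and by the bias-adjusted test. The list took 0.0783%, 0.0937% and 0.0415% of counts in apical replicates 1, 2 and 3, and 0.360%, 3.77% and 2.63% in basal replicates 1, 2 and 3 (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows).

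**Figure D1:**
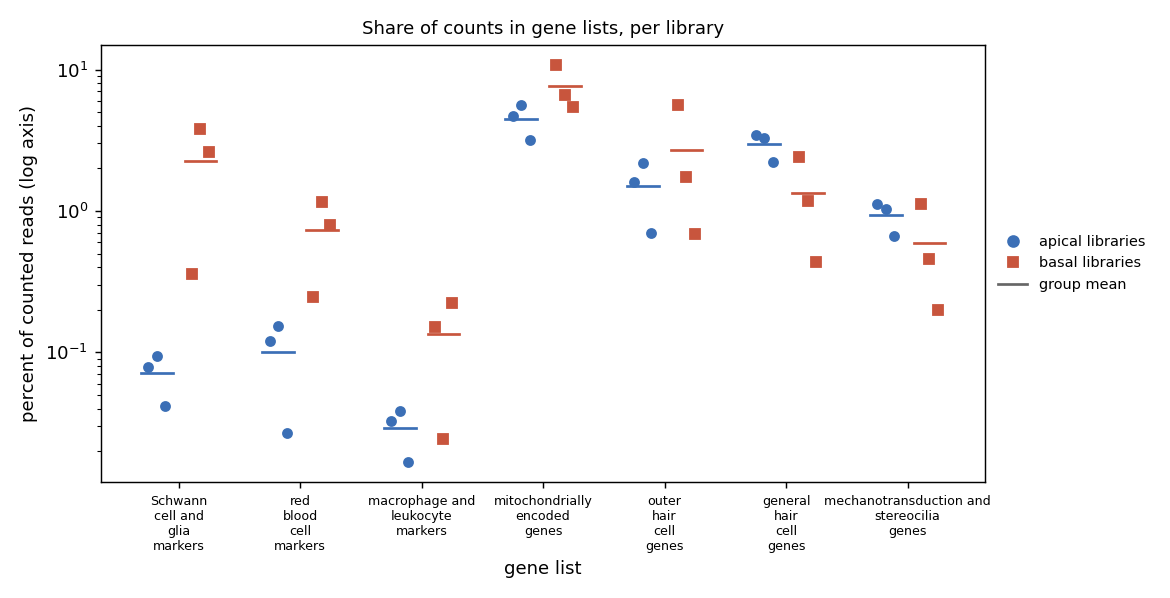
Percent of counted reads (log axis) taken by 7 gene lists in each of the 3 apical libraries (circles) and 3 basal libraries (squares), with the group mean as a bar. The Schwann cell share was 0.0415% to 0.0937% in apical libraries and 0.360% to 3.77% in basal libraries.

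Lists of macrophage, red blood cell and fibrocyte markers were also called. Of the macrophage and leukocyte markers, 13 of 15 were higher in basal libraries (camera adjusted p = 1.40e-07; adjusted p = 0.596 with an estimated correlation). Fcer1g, an immunoglobulin receptor subunit, had a log2 fold change of 4.62 (SE 1.09) and Lyz2 (lysozyme) one of 7.74 (SE 2.17). By edgeR's quasi-likelihood test neither passed over all genes, though both were among the 5 members that passed adjusted over the list alone. By DESeq2 both passed over all genes (adjusted p = 0.00129 and 0.00303), and Lyz2 also by the bias-adjusted test (adjusted p = 0.0387). The macrophage share did not separate the groups, at 0.0167% to 0.0385% in apical libraries and 0.152%, 0.0245% and 0.225% in basal replicates 1, 2 and 3. All 7 of 7 red blood cell markers were higher in basal libraries (camera adjusted p = 0.000418; adjusted p = 0.596 with an estimated correlation), among them Hba-a2 (log2 fold change 3.24, SE 0.75) and Hbb (3.02, SE 0.93), haemoglobin genes with near-identical copies whose reads can be split between them. Of the red blood cell markers 3 passed adjusted over the list alone, and adjusted p over all alternatives was 2.56e-05 to 0.837, the highest with the Schwann cell sum as a covariate, where the direction turned. Fibrocyte and mesenchyme markers were higher in 11 of 14 cases with a median of 0.95 (camera adjusted p = 0.00258; adjusted p = 0.596 with an estimated correlation). Col1a1, a collagen of bone and connective tissue, had a log2 fold change of 5.31 (SE 1.30) and did not pass. The fibrocyte call was lost without apical replicate 3 (adjusted p = 0.195) or basal replicate 2 (adjusted p = 0.109), and the range over all alternatives was 6.14e-05 to 0.973. With the Schwann cell sum as a covariate the list was called in the opposite direction (median -3.28, adjusted p = 0.0196). That sum lies apart between the groups, at 0.0415% to 0.0937% and 0.360% to 3.77% of counts, so a group difference adjusted for it is an extrapolation. With a library left out the fibrocyte median was 0.45 to 2.01. The fibrocyte share in basal replicate 1 was 0.142%, below the 0.290% to 0.418% of the apical libraries, and 0.880% and 0.946% in basal replicates 2 and 3.

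Genes of mechanotransduction and the stereocilia fell by camera (adjusted p = 0.000105, and 0.596 with an estimated correlation). By edgeR's quasi-likelihood test 0 of 43 members passed, either over all genes or adjusted over the list alone. DESeq2 called 5 members over all genes, all lower in basal libraries, and the authors' deposited table lists 2. Both genes named next, with edgeR values, were among the 5. Triobp, which bundles actin in stereocilia rootlets, had a log2 fold change of -1.68 (SE 0.37, adjusted p = 0.438), and Fscn2, an actin-bundling fascin, one of -3.30 (SE 0.81, adjusted p = 0.438). The list took 1.12%, 1.04% and 0.665% of counts in apical replicates 1, 2 and 3 and 1.13%, 0.460% and 0.201% in basal replicates 1, 2 and 3. Basal replicates 2 and 3, which had the lower values, were those with Schwann cell shares of 3.77% and 2.63%. General hair cell genes fell by camera (adjusted p = 0.00891; adjusted p = 0.596 with an estimated correlation), with shares of 2.41%, 1.18% and 0.434% in basal replicates 1, 2 and 3 beside the same Schwann cell shares. Otof (otoferlin, needed for transmitter release) had a log2 fold change of -2.43 (SE 0.59) and Ptprq, a phosphatase of the hair bundle, one of -2.38 (SE 0.79), and neither passed. The call on mechanotransduction genes was lost without basal replicate 3 (adjusted p = 0.313), and that on general hair cell genes without apical replicate 2 or basal replicate 3 (highest adjusted p = 0.794). The medians were -1.33 and -1.10 with the replicate number as a block. Over all alternatives adjusted p was 6.29e-08 to 0.875 and 4.71e-05 to 0.812. Camera's direction turned to higher in basal libraries with the Schwann cell sum as a covariate (medians 0.55 and 0.35, adjusted p = 0.405 and 0.491), which is again an extrapolation. It also turned, with the highest p-values and medians of -0.11, in a fit of 3 apical libraries against basal replicate 1 alone, chosen after seeing the data and without replication in the basal group.

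**Figure D2:**
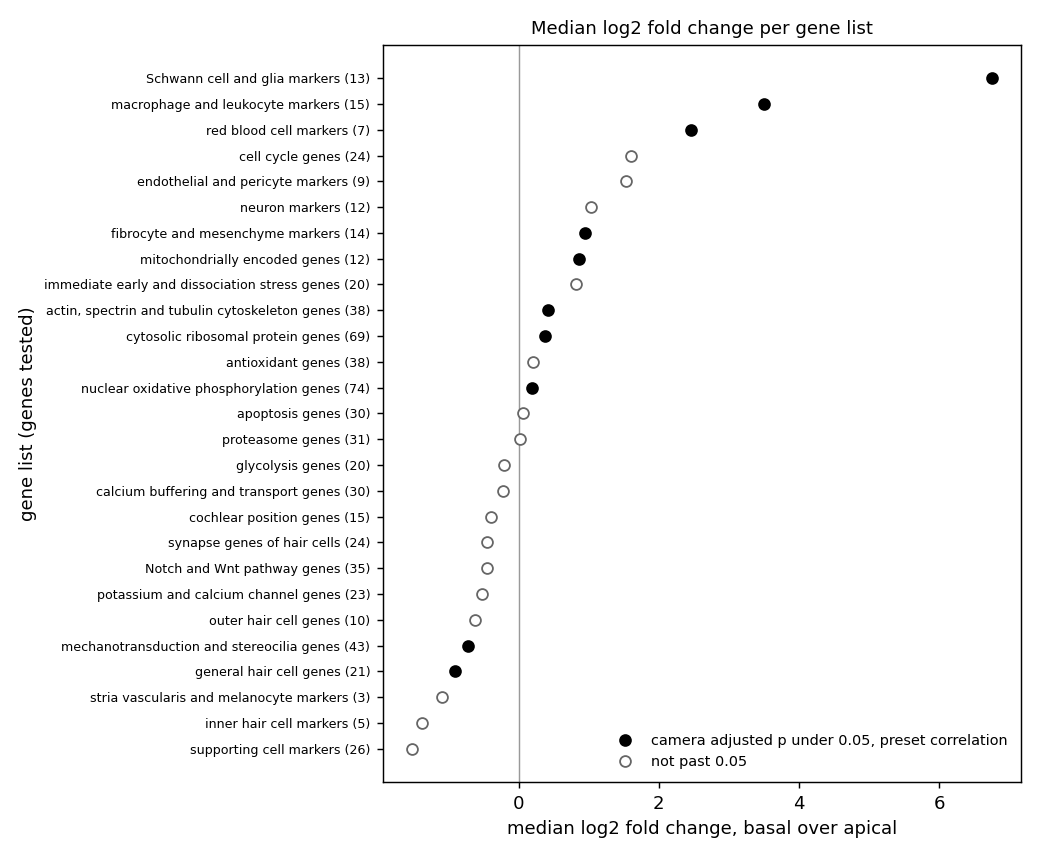
Median log2 fold change, basal over apical, of the tested members of each of 27 gene lists, with the number of tested genes in brackets. Filled circles mark the 10 lists with a camera adjusted p under 0.05 at the preset correlation, from -0.91 for general hair cell genes to 6.75 for Schwann cell and glia markers.

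Of the hair cell genes named in any case and tested, the subunits of the nicotinic receptor that receives efferent input had the smallest p-values. Chrna9 (ENSRNOG00000002484, chromosome 14, 43883458 to 43890171) was at 446 ± 203 CPM in apical and 90.2 ± 34.0 in basal libraries (SD, n = 3 each). Its log2 fold change was -2.31 (SE 0.51, edgeR adjusted p = 0.438). It passed by edgeR only adjusted over the list alone, and by DESeq2 over all genes (adjusted p = 0.0163). Chrna10 had a log2 fold change of -1.90 (SE 0.61), Slc26a5 (prestin, the motor protein of electromotility) one of -1.55 (SE 0.71), Calb1 one of -1.53 (SE 0.67), Tmc1 (a transduction channel subunit) one of -1.66 (SE 0.62) and Myo7a (a hair bundle myosin) one of -1.37 (SE 0.94). Oncomodulin, listed as Ocm2, had a log2 fold change of 1.33 (SE 0.93), Pou4f3, a hair cell transcription factor, one of 0.93 (SE 0.95), and Kcnma1, the large-conductance potassium channel, one of 0.45 (SE 0.91). None of these 9 genes passed by edgeR, with adjusted p from 0.438 to 1.00. The sign for Ocm2 turned without basal replicate 1 (-0.0882), that for Pou4f3 without basal replicate 1 (-1.02), and that for Kcnma1 without basal replicate 3 (-0.61). Slc17a8 was too low to be tested, with 26, 0 and 0 apical and 0, 0 and 61 basal counts.

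**Figure D3:**
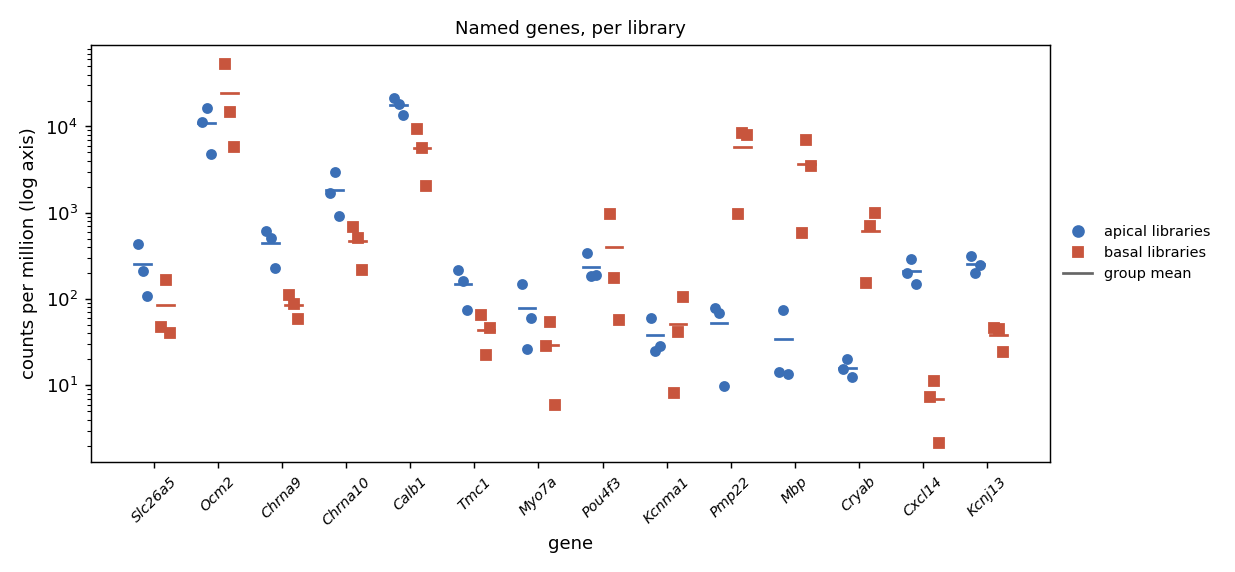
CPM by total count (log axis) of 14 named genes in each of the 3 apical libraries (circles) and 3 basal libraries (squares), with the group mean as a bar. Pmp22, Mbp and Cryab were higher in every basal than in every apical library, and Chrna9, Cxcl14 and Kcnj13 higher in every apical than in every basal library.

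Of the genes with separate groups and the smallest p-values, none passed by edgeR's main quasi-likelihood test (adjusted p from 0.325 to 0.438). By DESeq2 every gene named in this paragraph passed. By the bias-adjusted test Cryab, Crip1, Itm2a, Tmsb4x, Cxcl14 and Hsd17b14 passed and the others of this paragraph did not. These genes had been picked for separate groups and small p in the same counts, so such passes are no separate support. On simulated counts DESeq2 called 216 genes that had not been changed, and the bias-adjusted test 25. Higher in basal libraries were Cryab, a small heat shock protein (log2 fold change 5.28, SE 0.71), Crip1 (3.90, SE 0.61), Itm2a (4.62, SE 0.81), Tmsb4x, an actin-binding thymosin (2.48, SE 0.45), Cst3 (cystatin C; 2.14, SE 0.39) and Tagln2 (3.25, SE 0.60). Fa2h, which makes hydroxylated lipids of myelin, had 2, 0 and 0 apical against 556, 1254 and 934 basal counts, a ratio of summed rates of 1604 (95% interval 444 to 13249). Higher in apical libraries were Cxcl14, a chemokine (-4.88, SE 0.73), Kcnj13, an inward rectifier potassium channel (-2.66, SE 0.45), Prkag2 (-3.25, SE 0.60), Lsr (-2.81, SE 0.52) and Sept6 (-2.22, SE 0.41). Il1r2, a decoy receptor for interleukin-1, had 1092, 644 and 2289 apical counts and 0 in each basal library, which makes it at least 1148-fold higher in apical libraries against a floor of 3 counts over the group. With a single basal count each, Hsd17b14 was 3769-fold higher in apical libraries (95% interval 676 to 148916; 1278, 1376 and 1752 apical counts) and Dnai2, a ciliary dynein chain, 1814-fold (325 to 71670; 675, 847 and 598 counts). Gal (galanin), also with a single basal count, was 5216-fold higher (936 to 206056), with most of its 486, 724 and 4887 apical counts in apical replicate 3. Pkhd1l1, a coat protein of stereocilia, had 855, 1786 and 562 apical and 2 basal counts and was 1370-fold higher (379 to 11318). These intervals cover counting error only.

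Mitochondrially encoded genes rose by camera, with 12 of 12 higher in basal libraries and a median of 0.87 (adjusted p = 0.000105; adjusted p = 0.596 with an estimated correlation), among them Mt-nd3 (1.26, SE 0.46) and Mt-nd4l (0.81, SE 0.39). Their share was highest in basal replicate 1 (10.8%), the basal library with the lowest Schwann cell share. Cytosolic ribosomal protein genes rose by a median of 0.38 with 67 of 69 higher (adjusted p = 9.50e-07; adjusted p = 0.596 with an estimated correlation), with Rpl35 at 0.68 (SE 0.35) and Rpl13a at 0.66 (SE 0.36); many have processed pseudogenes that can share their reads. Cytoskeleton genes rose by a median of 0.42 with 25 of 38 higher (adjusted p = 0.0165; adjusted p = 0.596 with an estimated correlation), Tmsb4x having the smallest p while Tubb4a lay at -2.03 (SE 0.49). Nuclear oxidative phosphorylation genes rose by a median of 0.19 with 51 of 74 higher (adjusted p = 0.0271; adjusted p = 0.697 with an estimated correlation), with Uqcrc2 at -1.07 (SE 0.45) and Atp5j2 at 0.81 (SE 0.43). The ribosomal call was lost without apical replicate 1 (adjusted p = 0.0565), the cytoskeleton call without basal replicate 2 or 3 (highest adjusted p = 0.102) and the oxidative phosphorylation call without apical replicate 1 or 3 or basal replicate 1 (highest adjusted p = 0.705). With a library left out the medians were 0.47 to 1.07 for mitochondrially encoded, 0.15 to 0.62 for ribosomal protein and 0.22 to 1.00 for cytoskeleton genes. That of oxidative phosphorylation genes was -0.036 to 0.34, changing sign without basal replicate 1. For cytoskeleton genes camera's direction turned with the Schwann cell sum as a covariate (adjusted p = 0.741), which is an extrapolation. Their median was -0.75 with basal replicates 2 and 3 left out. Adjusted over the list alone, Tmsb4x passed among cytoskeleton genes and no mitochondrially encoded, ribosomal protein or oxidative phosphorylation gene did.

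The other 17 lists did not pass by camera with all 6 libraries. Of these, 8 passed in some fits with a library left out (adjusted p from 2.41e-05 to 0.0424). Neuron markers passed without any 1 of the apical libraries or basal replicate 1. Endothelial and immediate early genes passed without apical replicate 1 or 3 or basal replicate 1. The others were stria vascularis markers (without apical replicate 3 or basal replicate 2), supporting cell markers (without apical replicate 2 or basal replicate 2), cell cycle genes (without basal replicate 1 or 2), channel genes (without apical replicate 3) and synapse genes (without basal replicate 1). Lower medians were found for supporting cell markers (-1.52, adjusted p = 0.0691), inner hair cell markers (-1.38, adjusted p = 0.0961), stria vascularis and melanocyte markers (-1.09, adjusted p = 0.0749), outer hair cell genes (-0.62, adjusted p = 0.563), potassium and calcium channel genes (-0.52, adjusted p = 0.129), Notch and Wnt pathway genes (-0.45, adjusted p = 0.517), synapse genes (-0.45, adjusted p = 0.177), cochlear position genes (-0.40, adjusted p = 0.311), calcium buffering and transport genes (-0.23, adjusted p = 0.794) and glycolysis genes (-0.21, adjusted p = 0.647). Higher medians were found for cell cycle genes (1.61, adjusted p = 0.0904), endothelial and pericyte markers (1.54, adjusted p = 0.0904), neuron markers (1.03, adjusted p = 0.0569), immediate early and dissociation stress genes (0.82, adjusted p = 0.0822), antioxidant genes (0.21, adjusted p = 0.148), apoptosis genes (0.06, adjusted p = 0.581) and proteasome genes (0.02, adjusted p = 0.602). Camera's direction was opposite to the median for calcium buffering genes, and the mean was opposite to the median for apoptosis (-0.10) and proteasome genes (-0.04). The inner hair cell median was -2.14 to 0.54 with a library left out, changing sign without apical replicate 3 while camera's direction did not turn. For neuron markers it was 0.30 to 2.31. Tectb, a protein of the tectorial membrane that is in the supporting cell and cochlear position lists, had a log2 fold change of -3.72 (SE 0.76). Snap25, a synaptic protein in the synapse and neuron lists, had one of 2.27 (SE 0.46). By edgeR's quasi-likelihood test neither passed over all genes, while by DESeq2 both did (adjusted p = 0.0017 and 3.4e-05). Tectb also passed by the bias-adjusted test (adjusted p = 0.0446). Adjusted over the list alone, 4 synapse, 3 channel, 2 inner hair cell, 2 supporting cell and 2 neuron list members passed. So did 1 member each of the outer hair cell, stria vascularis, immediate early and cochlear position lists. In the other 8 of these lists 0 passed. The 4 synapse list members include Pkhd1l1, a coat protein of stereocilia. The immediate early member is Egr2, which is also in the Schwann cell list. It had 1, 0 and 0 apical and 98, 922 and 427 basal counts.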

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

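Of the tests in this part, the bias-adjusted and likelihood ratio tests, the Schwann covariate, basal replicates 2 and 3 left out, DESeq2 and bias-adjusted fits with a library left out, and all GO tests were chosen after the result was seen. The edgeR count of 0 genes stayed at 0 with the 3 other scalings, the stricter filter, robust dispersions, the gene removals, the Schwann covariate and the limma tests. It was 8 with a filter of at least 1 count in any library, 28 with the bias-adjusted test, 327 with the likelihood ratio test, 663 with DESeq2 and 289 with basal replicates 2 and 3 left out (3 libraries against 1, the single basal library being assumed to vary like the apical ones), and 0 to 2 with each library left out, the 2 arising without basal replicate 1. DESeq2 gave 700 to 1703 genes with a library left out, and above 1.5 times its own count without basal replicate 1 (1231) or 3 (1703). The bias-adjusted test gave 0 to 189, being 0 without any library but basal replicate 1. The 10 gene lists became 0 with an estimated correlation, 0 with fry, 4 with the Schwann covariate and 5 with basal replicates 2 and 3 left out, and 7 to 14 with a library left out; 4 of the 10 kept their call without each library in turn. The 39 GO terms became 0 with an estimated correlation, 0 with the Schwann covariate, 19 with basal replicates 2 and 3 left out, and 9 to 69 with a library left out (25 without apical replicate 3, 69, 9 and 12 without basal replicates 1, 2 and 3). The cause was not tested, except that fewer libraries enter the fits with libraries left out. The Schwann cell log2 difference in shares ranged from 3.85 to 5.55. Samples share only a replicate number: same-numbered deviations correlated at -0.0384, 0.00667 and 0.138, apical replicates 1 and 2 and basal replicate 1 did not correlate best with their own number, and the replicate block gave 0 genes, 11 lists (supporting cell markers added, adjusted p = 0.0385) and 34 GO terms.

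Of 1629 log2 fold changes of 72 named genes under 23 settings, 1499 kept direction and side of the threshold, 109 passed it newly and 21 reversed; of 324 list results, 236 were the same, 36 lost and 19 gained the call and 33 reversed. The Schwann covariate lies apart between the groups (0.0415% to 0.0937% of counts in apical and 0.360% to 3.77% in basal libraries), so group differences adjusted for it are extrapolations. Reversed with the Schwann covariate were Col1a1 (-2.20), Nefh (-1.37), Hbb (-0.66), Ptprq (0.0647), Mgst3 (-0.48), Wnt7a (1.62), Fzd9 (0.13), Mcm4 (-8.98), Cdh5 (-11.71) and Kcnma1 (-3.86), and with basal replicates 2 and 3 left out Mcm4 (-2.69), Cdh5 (-4.92) and Kcnma1 (-2.03). Pou4f3 reversed with the replicate block (-0.0339), limma-voom (-0.0954), its sample quality weights (-0.59) and log2(FPKM + 1) (-0.0791), where Kcnma1 did too (-0.0198). With a library left out the log2 fold change of Ocm2 ranged from -0.0882 to 1.80 and the log2 fold change of Pou4f3 from -1.02 to 1.46, both reversed without basal replicate 1, and Kcnma1 from -0.61 to 0.98, reversed without basal replicate 3. List directions reversed with the Schwann covariate, by adjusted p, for outer hair cell genes (0.506), general hair cell genes (0.491), mechanotransduction and stereocilia genes (0.405), synapse genes (0.491), neuron (0.491), red blood cell (0.837), endothelial (0.506) and fibrocyte markers (0.0196), cochlear position (0.837), cytoskeleton (0.741), cell cycle (0.405) and proteasome genes (0.796). With basal replicates 2 and 3 left out they reversed for outer hair cell (0.379), general hair cell (0.812), mechanotransduction (0.875), synapse (0.875), apoptosis (0.942), cell cycle (0.812) and proteasome genes (0.812) and neuron markers (0.971). With fry they reversed for calcium buffering (0.512), apoptosis (0.680) and proteasome genes (0.727). With a library left out some fits reversed, the range over all 6 being 0.160 to 0.922 for outer hair cell genes (reversed without apical replicate 2 or basal replicate 3), 0.624 to 0.982 for calcium buffering, 0.383 to 0.982 for glycolysis and 0.369 to 0.982 for Notch and Wnt pathway genes (each without apical replicate 3 or basal replicate 1), 0.00463 to 0.762 for cell cycle genes (without basal replicate 3) and 0.349 to 0.941 for proteasome genes (without apical replicate 1). The cause was not tested.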

Other observations

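The tests on GO terms, the look-up of bone genes, all tests of splits and all tests of explanations in this part except that with the 3 other scalings were chosen after the result was seen. Genes annotated to the assembly of the axoneme, the microtubule core of motile cilia, fell as a group in the basal libraries by camera, with 20 of 25 lower and a median log2 fold change of -1.58 (adjusted p = 8.76e-05 over 5656 GO terms; adjusted p = 1.00 with an estimated correlation). Rsph1, Drc1, Hydin, Ccdc114 and Spag6, named after their values were seen, had 0 counts in every basal library. Rsph1 had 154, 398 and 600 apical counts and was at least 329-fold higher in apical libraries, and Hydin had 178, 319 and 372 and was at least 248-fold higher. Cilium movement genes, which share members with the axoneme term, had a median of -1.43 with 21 of 24 lower (adjusted p = 0.00111; adjusted p = 1.00 with an estimated correlation). The axoneme call was kept without each library in turn (highest adjusted p = 0.0280), but its median moved to -4.90 without basal replicate 3 and to -4.62 with the replicate block. It was lost with the Schwann covariate (adjusted p = 0.596) and with 3 apical libraries against basal replicate 1 alone (adjusted p = 0.174). The median was further from 0 in both of these fits, at -7.76 and -6.96, and why the calls ended was not tested; the covariate lies apart between the groups, so the first is an extrapolation. Collagen trimer genes rose by a median of 1.49 with 36 of 42 higher (adjusted p = 8.76e-05), and myelination genes by a median of 0.58 with 55 of 80 higher (adjusted p = 0.000532); both had an adjusted p of 1.00 with an estimated correlation.

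Ibsp (bone sialoprotein), singled out after the data were seen as the most abundant gene of basal replicate 3, had 698, 9222 and 25308 counts in apical and 2344, 24763 and 376822 in basal replicates 1, 2 and 3 (edgeR adjusted p = 0.932). Of 12 bone-related genes looked up then, 11 were tested by edgeR, 10 with a higher and 1 (Postn) with a lower estimate in basal libraries. By edgeR 0 passed (adjusted p from 0.438 to 1.00), 4 had an unadjusted p under 0.05, and 1 passed by DESeq2 (Col1a1) and 1 in the authors' deposited table (Dmp1). The higher estimates were uneven between basal libraries. Alpl had 635, 215 and 1217 apical and 332, 573 and 16141 basal counts, and Runx2 60, 29 and 36 against 69, 17 and 1164. Dmp1 (160, 0 and 37 against 975, 777 and 1193) and Phex (86, 0 and 2 against 214, 348 and 908) were higher in every basal than in every apical library. Col1a1, Postn and Sparc are also in the fibrocyte list. No list of bone genes was tested as a set.

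The 6 libraries can be split into 3 and 3 in only 10 ways, too few for a share under 0.05. An edgeR count of 0 genes is met by any split (10 of the 10 splits, highest other 0), so it says nothing about chance. The bias-adjusted count of 28 was met by 1 of the 10 splits (the real one; highest other 0) and the 10 lists by 1 of the 10 splits (highest other 9). The DESeq2 count of 663 was met by 2 of the 10 splits, since apical replicates 1 and 3 with basal replicate 3 against the rest gave 703. The 39 GO terms were met by 2 of the 10 splits. The other, apical replicate 1 with basal replicates 2 and 3 against the rest, gave 270, several times the real count. That split gave 9 lists, 209 DESeq2 genes and 0 bias-adjusted genes, each below the real count. Whether the samples hold a structure other than the groups was not tested. Principal components, the main axes of spread in log2 CPM, describe it only. On the first (34.1% of variance) apical replicates 1, 2 and 3 lay at -102, -104 and -110 and basal ones at 77.8, 276 and -38.7. On the second (30.8%) apical ones lay at 41.1, -21.9 and 49.3 and basal ones at -280, 118 and 93.3. On both axes the basal libraries covered a wider range than the apical ones.

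By camera, Schwann cell and glia genes were higher in the basal libraries in 13 of 13 cases (adjusted p = 3.33e-16). That call was lost with an estimated correlation (0.596) and with fry (0.137). By edgeR's quasi-likelihood test 0 members passed over all genes, and by DESeq2 9 did. The log2 ratio of group mean library sizes was -0.23 while the members had a median of 6.75. Counts had been scaled for library size before that median was taken, so this is no test of a difference in library size. A candidate explanation is RNA of Schwann cells carried along with the picked cells, under which the members' ratios would be alike between basal libraries. Their spread was 0.853 against a median of 1.10 for random lists matched on basal level, at the 17.2th percentile of 10000 lists, which is not low enough to decide. The most abundant members were Pmp22 and Mbp, at 5653 and 3635 CPM on average in basal libraries; 2 of the 13 members are in another list and 6 had at least 10 counts in every apical library, and picking of cells under the microscope would remove whole Schwann cells. This explanation and a difference between turns in the cells themselves, which was not tested, stay open.

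By camera, mechanotransduction and stereocilia genes were lower in the basal libraries in 36 of 43 cases (adjusted p = 0.000105). That call was lost with an estimated correlation (0.596) and with fry (0.186). By edgeR's quasi-likelihood test 0 members passed over all genes, and by DESeq2 5 did. The list's median lay -0.70 from that of all genes tested, which restates camera's comparison with all other genes and is no test of a scaling shift shared by all genes. The 3 other scalings, under which the list's median was at most -0.64, decide nothing, since they moved all genes by at most 0.0736. Dilution of hair cell RNA by RNA of other cells may lower all hair cell genes alike. The other members of the hair cell lists differed from the list by a median of -0.0855 (95% bootstrap interval -0.82 to 0.68), an interval too wide to decide. Genes were resampled with the libraries fixed, so the interval leaves out the spread between libraries. Dilution and a difference between turns, which was not tested, cannot be told apart.

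By camera, axoneme assembly genes were lower in the basal libraries in 20 of 25 cases (adjusted p = 8.76e-05), a call lost with an estimated correlation (adjusted p = 1.00). Of the members, 24% were under 3 counts in all 3 basal libraries, against 0% to 8% (95% range) in random lists matched on apical level, but the term had been picked for being lower, so this does not decide whether dropout of moderately expressed genes in the basal libraries is the cause. Dilution of hair cell RNA may contribute, but the difference of medians from the hair cell lists was -0.74 (95% bootstrap interval -5.36 to 0.51), too wide to decide. For this interval too, genes were resampled with the libraries fixed. A difference between turns in the number of cells with such transcripts stays open as a hypothesis and was not tested.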
